A study of Mus musculus with 28 samples.

How the data were processed

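The series holds 28 libraries from 14 islet samples of mice. Ctl contributed 6 samples, LIRKO 4 and LIRKO_HFD 4, and each sample gave an input library and a library of RNA immunoprecipitated (IP) with an antibody against N6-methyladenosine (m6A). Per the labels' protocols, hand-picked islets were cultured overnight at 7 mM glucose in medium with 10% FBS. Per the same protocols, RNA was extracted with TRIzol, enriched on polyT beads and fragmented by ultrasound, and the m6A fraction was taken with an EpiMark kit before Kapa library construction. The labels give the cell type as beta cell, while the protocol describes whole islets, so the samples are called islets here.

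The submitters' processing notes name fastp, STAR and deepTools and the genome build mm39, without versions. The deposited coverage table holds, per its values, a whole-number read count for each library in 54606106 bins of 50 bp over 61 chromosomes and scaffolds. It is not normalized, and 1 read can count in more than 1 bin, so totals are called bin reads. The 14 deposited peak lists, 1 per sample, carry the name of the peak caller Piranha, whose version and options are not given in the sources used here. In each list the deposited peak height is a signal equal to the mean m6A read count per bin of the peak. A further deposited column holds the p-value that Piranha gave each peak, none above 0.05. The last deposited column holds the natural log of the input read count, averaged over the peak's bins. The lists mark every peak as on the plus strand, so strand was not used. Peaks were called by the authors per sample and not on pooled samples, as the 14 separate lists show. The library totals ranged from 156705424 to 188436924 bin reads for inputs and from 195120597 to 247039732 for m6A libraries.

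The only annotation at hand belongs to another mouse assembly (GRCm38.p6), and the files hold no gene identifiers. No gene was therefore named, and regions are given by mm39 coordinates counted from 1. The tests of gene lists, of peaks near stop codons and of the insulin receptor gene were not run for that reason, nor was the alternative that counts whole gene bodies. The design written before the data were examined counted reads per gene. Its place was taken by 87671 transcribed segments, made of bins with at least 10 reads in at least 4 of the 14 inputs and joined over gaps of up to 1000 bp. For m6A, peaks of the 14 lists were merged, and 77282 consensus peaks found in at least 3 samples were counted in all 28 libraries.

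RNA was compared with the quasi-likelihood test of edgeR 4.0.16 on the counts of the 14 inputs of all 3 conditions, with TMM scaling and edgeR's expression filter, which kept 85209 segments. The m6A change was tested with edgeR in 1 model over all 28 libraries, as the interaction of condition with IP against input, with the sample as a block. The block rests on the protocol, which makes both libraries of a sample from the same mRNA. A segment or peak was called at a Benjamini-Hochberg adjusted p under 0.05. Since TMM centres the average feature, any change common to most peaks or segments would not be seen. Levels are given as log2 CPM after TMM with a prior count of 1, and m6A as the log2 ratio of IP to input on that scale. Peak numbers and library shares were compared with two-sided exact permutation tests, and their 18 p-values were adjusted together by Benjamini-Hochberg. With 6 samples against 4 there are 210 splits and the smallest possible p is 0.00476, and with 4 against 4 there are 70 splits and it is 0.0286.

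Named segments follow a rule fixed before the data were examined: the largest changes in each direction among called segments with a mean log2 CPM of at least 3 and no overlap between the libraries of the 2 conditions. Named peaks follow the same rule at a log2 CPM of at least 0, with 1 peak per locus. The rule allowed 6 segments and 5 peaks per direction, of which the first 2 are printed because they have no gene names. Loci, meaning called segments joined over gaps of up to 50 kb, and the sex chromosome regions were chosen after their values were seen. The 100 most covered bins fall in 24 loci, and segments or peaks within 600 kb of those are called near an abundant locus.

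Both edgeR fits were tested on simulated counts for LIRKO against Ctl. These counts were drawn for each library on its own, around the mean profile of its fraction, at the real library sizes. The simulation held no structure shared between samples or between the IP and input of a sample. Its numbers therefore do not give error rates for data with such structure, which is described below. Over 85209 segments the RNA fit recovered 27 of 100 segments changed 2-fold and 72 of 100 changed 4-fold, and 9 of its 108 calls were false. Over 77282 peaks the m6A fit recovered 28 of 100 peaks changed 2-fold and 68 of 100 changed 4-fold, and 8 of its 104 calls were false.

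The alternatives tried were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors or library totals in place of TMM, no low-count filter or a mean log2 CPM of at least 1, and the replicate number as a block for RNA or no block for m6A. Others were a fit of the 2 compared conditions alone, every other bin, counts thinned to the shallowest library, consensus peaks found in at least 7 or at least 1 sample, and stricter, merged or autosomal and X peak lists. Each sample was also left out in turn. Alternatives added after the data were examined were 10-kb windows, segments joined over 200 bp, regions near abundant loci or on the Y chromosome left out, the share of covered bins as a covariate, minimum peak heights, other forms of the mitochondrial and covered-bin shares, and a pair of joint sample exclusions. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.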

Results

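Messenger RNA and its m6A fraction were sequenced from islets of Ctl mice, of LIRKO mice, which lack the insulin receptor in the liver per the series title, and of LIRKO_HFD mice. The labels do not spell out HFD, which customarily stands for high-fat diet. There were 6 Ctl, 4 LIRKO and 4 LIRKO_HFD samples, each with an input and an m6A library. Inputs held 156705424 to 188436924 bin reads, meaning reads summed over bins of 50 bp, and m6A libraries 195120597 to 247039732. The labels do not state that the samples came from separate animals, so p-values measure the spread between these samples. Intervals and floors cover counting error only.

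A few loci held much of the RNA. The region chr16:10961841-10962140 (mm39, as all coordinates here) took 10.0% ± 0.434 (SD, n = 6) of the Ctl input reads, 12.2% ± 1.54 (n = 4) of the LIRKO ones and 12.8% ± 0.726 (n = 4) of the LIRKO_HFD ones. Its share of the m6A libraries was lower, at 1.03% ± 0.214, 1.71% ± 0.0525 and 1.55% ± 0.171 in the same order. The region chr7:142232375-142233474 went the other way, with 2.79% ± 0.236 of the Ctl input reads and 12.9% ± 5.01 of the Ctl m6A reads. In LIRKO it took 2.87% ± 0.744 of the input and 15.5% ± 4.78 of the m6A reads, and in LIRKO_HFD 1.78% ± 0.267 and 10.2% ± 0.618. The 100 most covered bins together held 46.8% ± 4.52 of the Ctl, 52.3% ± 3.50 of the LIRKO and 48.6% ± 0.614 of the LIRKO_HFD input reads.

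The mitochondrial genome took 3.80% ± 0.539 (SD, n = 6) of the Ctl, 3.43% ± 1.20 (n = 4) of the LIRKO and 2.04% ± 0.0337 (n = 4) of the LIRKO_HFD input reads. It was lower in every LIRKO_HFD input than in every Ctl and LIRKO input. The exact two-sided permutation p was 0.00476 against Ctl and 0.0286 against LIRKO, each the smallest its design allows, with adjusted values of 0.0571 and 0.0735 over 18 tests. LIRKO and Ctl did not differ beyond the spread (exact permutation p = 0.505). Without any 1 of the LIRKO_HFD samples the exact permutation p against LIRKO was 0.0857, and in the m6A libraries the difference from LIRKO was -0.62 percentage points with an exact permutation p of 0.314.

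The libraries also differed in how much of the genome they covered. Ctl inputs had reads in 13.5% ± 2.05 (SD, n = 6) of the genome bins, LIRKO inputs in 9.10% ± 3.13 (n = 4) and LIRKO_HFD inputs in 9.26% ± 0.697 (n = 4). The exact two-sided permutation p was 0.0333 for LIRKO against Ctl (adjusted 0.075) and 0.00952 for LIRKO_HFD against Ctl (adjusted 0.0571). Breadth differed within groups too, from 5.56% to 12.7% among the LIRKO inputs and from 10.3% to 16.0% among the Ctl ones. All LIRKO_HFD inputs, at 8.39% to 9.93%, lay below every Ctl one. A fit with the share of covered bins as a covariate therefore cannot separate breadth from LIRKO_HFD against Ctl. For LIRKO against Ctl it can do so only in part. The exact permutation p for LIRKO against Ctl was 0.0556 without Ctl 1, 0.0635 without Ctl 2, 3 or 5, 0.0714 without LIRKO 1 and 0.0833 without LIRKO 2.

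The immunoprecipitation was compared with input at the consensus peaks. Of 77282 peaks, 19201 (24.8%) held more IP than input reads after TMM scaling in all 3 conditions and 18068 held fewer, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. This split depends on the scaling, which sets the average peak to near 0. With library totals 63896 peaks were higher in all 3 conditions and 802 lower.

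The comparison of LIRKO with Ctl asks what the loss of the hepatic insulin receptor changes in islet RNA. At chr9:95283291-95289390 the input level was 3.04 ± 1.72 log2 CPM (SD, n = 4) in LIRKO and 0.98 ± 0.13 (n = 6) in Ctl. At chr9:56140767-56140816, near an abundant locus, it was 6.19 ± 0.46 in LIRKO and 5.18 ± 0.31 in Ctl. The level of chr12:8054813-8066762 was 2.06 ± 0.86 in LIRKO and 4.49 ± 0.84 in Ctl, and that of chr8:9579647-9600474 was 2.65 ± 0.41 and 4.13 ± 0.48. The fitted log2 changes were 2.72 (adjusted p = 0.0174), 1.03 (0.0204), -2.42 (0.0262) and -1.50 (0.0174) in that order, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That test called 364 segments higher and 308 lower, in 347 loci. Of the 672 called segments 11.8% lay near an abundant locus, against 2.17% of those tested. Without LIRKO 1 and 2 the log2 change at chr9:95283291-95289390 was 0.59. With the share of covered bins as a covariate none of these 4 segments was called, and the changes at chr12:8054813-8066762 and chr8:9579647-9600474 were -1.11 and -0.88.

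Called segments that lay close together were joined into loci, chosen after their values were seen and for a shared direction. Segments there that were not called do not enter, so agreement of neighbours was not tested. The locus chr8:9456035-9813420 held 42 called segments, all lower, with a median log2 change of -1.35. Its median level was 0.38 ± 0.28 log2 CPM (SD, n = 4) in LIRKO, 1.72 ± 0.44 (n = 6) in Ctl and 1.13 ± 0.16 (n = 4) in LIRKO_HFD. At chr9:68590763-68745952 the 9 called segments fell by a median of 1.28 on the log2 scale. The locus chr7:130633719-130723602, near an abundant locus, held 33 called segments, all higher, with a median log2 change of 3.53. Its level was 4.07 ± 2.13 in LIRKO, 1.24 ± 0.86 in Ctl and 5.97 ± 0.22 in LIRKO_HFD. At chr3:113030361-113263934, with 12 called segments, the level was 5.88 ± 1.74 in LIRKO, 2.60 ± 1.11 in Ctl and 7.73 ± 0.23 in LIRKO_HFD. The rises rested on LIRKO samples 1 and 2. Without both of them the median log2 change was 0.87 at chr7:130633719-130723602 and 1.28 at chr3:113030361-113263934, and that of chr8:9456035-9813420 was -1.12.

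The number of called segments depended on the samples and on the fit. The 672 calls became 0 in a fit of the 2 conditions alone, where 12379 segments had an unadjusted p under 0.05, and 2926 with DESeq2. With the share of covered bins as a covariate 109 were called, 1 of them higher. Breadth differed between the 2 conditions as well, so this drop does not show that breadth set the calls. Leaving out 1 sample gave 0 calls without LIRKO 1 (10073 at an unadjusted p under 0.05), 0 without LIRKO 2 (9845), 1 without Ctl 2, 1 without Ctl 5, 10 without Ctl 1, 432 without Ctl 3, 1749 without LIRKO 4 and 2225 without Ctl 6.

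**Figure D1:**
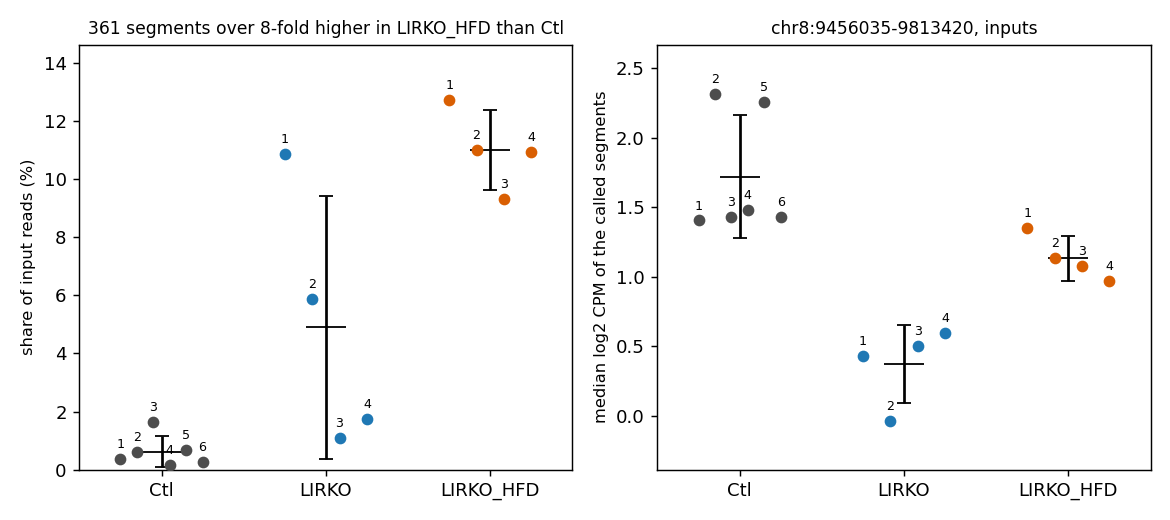
Left, the share of input reads (%, vertical axis) in 361 segments over 8-fold higher in LIRKO_HFD than in Ctl; right, the median log2 CPM of the segments called at chr8:9456035-9813420. Points are input libraries numbered by replicate and bars are the mean ± SD of each condition; LIRKO 1 and 2 held 10.9% and 5.88% in the left plot, the other LIRKO inputs 1.08% and 1.74%.

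For m6A, LIRKO and Ctl were compared at the same peaks. The IP to input ratio of chr3:148758081-148758580 was 7.62 ± 1.75 on the log2 scale (SD, n = 4) in LIRKO and 2.85 ± 0.93 (n = 6) in Ctl. At chr1:22594975-22595074 it was 8.08 ± 2.32 in LIRKO and 2.46 ± 1.20 in Ctl. Both rest on few input reads in LIRKO, 0 to 149 at the first and 0 to 60 at the second, so the size of these ratios depends on the prior count. The ratio was lower in LIRKO at chr17:32476679-32477078, at -0.14 ± 0.39 against 1.18 ± 0.46, and at chr6:47464189-47464588, at 0.83 ± 0.37 against 2.08 ± 0.28. The fitted log2 changes were 3.74 (adjusted p = 0.00136), 3.91 (0.025), -1.33 (0.0186) and -1.25 (0.0295) in that order, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That test called 169 peaks higher and 43 lower, and with library totals 88 higher and 7 lower. Of the 212 called peaks 23.6% lay near an abundant locus, against 2.07% of those tested, and 92 had a mean log2 ratio below 0 in both conditions.

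Without the sample as a block 9 peaks were called, without any of the 4 named peaks, and DESeq2 called 1355. Single samples moved the number, with 1413 calls without LIRKO 2, 67 without LIRKO 3, 78 without Ctl 5, 80 without LIRKO 1, 81 without LIRKO 4, 102 without Ctl 2, 115 without Ctl 4 and 120 without Ctl 1.

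**Figure D2:**
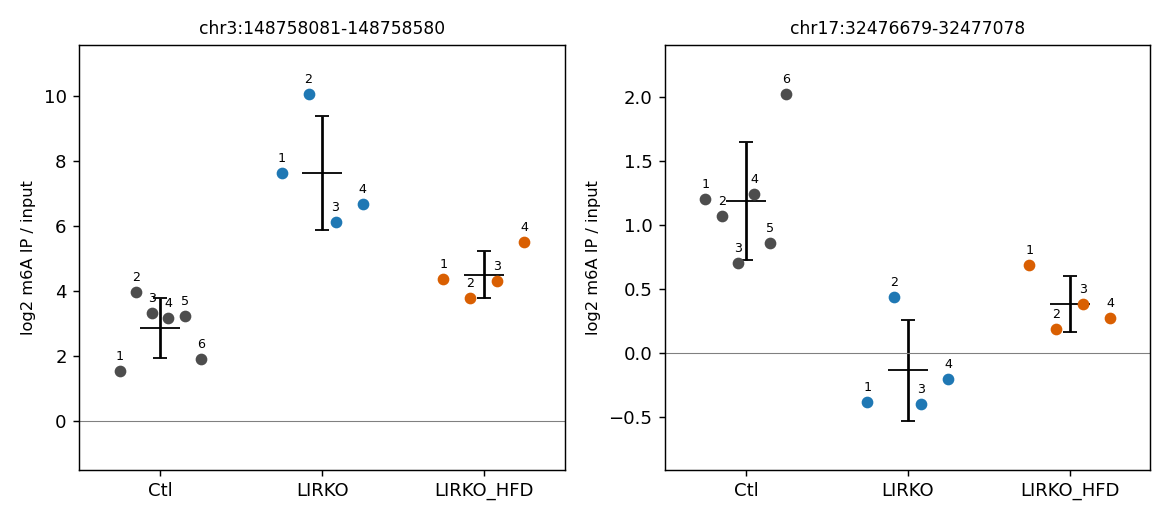
The log2 ratio of IP to input CPM (vertical axis) at chr3:148758081-148758580 and chr17:32476679-32477078 in each sample. Points are samples numbered by replicate and bars are the mean ± SD of each condition; the means were 7.62 in LIRKO and 2.85 in Ctl at the first peak, and -0.14 and 1.18 at the second.

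The comparison of LIRKO_HFD with Ctl joins the knockout with the second factor of the labels. At chr17:28779495-28779794 the input level was 7.84 ± 0.29 log2 CPM (SD, n = 4) in LIRKO_HFD and 2.28 ± 1.02 (n = 6) in Ctl. At chr6:41331025-41331174 it was 4.53 ± 0.50 in LIRKO_HFD and -1.69 ± 1.77 in Ctl. Lower levels were seen at chr9:114500439-114500588, with 3.47 ± 0.23 in LIRKO_HFD and 4.51 ± 0.36 in Ctl, and at chr16:42236671-42236820, with 3.14 ± 0.23 and 4.16 ± 0.30. The fitted log2 changes were 5.28 (adjusted p = 0.00115), 5.38 (0.00481), -1.07 (0.00819) and -1.04 (0.0075) in that order, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That test called 966 segments higher and 192 lower, in 489 loci, and 36 of the lower and 4 of the higher ones lay on the Y chromosome. Of the 1158 called segments 15.4% lay near an abundant locus, against 2.17% of those tested.

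Among loci chosen after their values were seen, chr7:130633719-130723602, near an abundant locus, held 33 called segments with a median log2 change of 4.53. The locus chr6:41274819-41521520 held 22 with 4.68. Smaller rises covered chr16:10683211-11281098, near an abundant locus, where 42 segments had a median log2 change of 1.06 and the level was 3.02 ± 0.12 log2 CPM (SD, n = 4) in LIRKO_HFD and 1.95 ± 0.29 (n = 6) in Ctl. The level of chr7:130174921-130487178, near an abundant locus as well and over 23 called segments, was 3.36 ± 0.27 in LIRKO_HFD and 2.43 ± 0.19 in Ctl. With library totals the median log2 changes were 0.52 at chr16:10683211-11281098 and 0.42 at chr7:130174921-130487178, and few of their segments were called. At chr5:145791497-145816674, near an abundant locus and with 9 called segments, the level was -5.22 ± 1.63 in LIRKO_HFD and -0.44 ± 0.99 in Ctl. At chr6:47631907-47662334, with 8, it was 1.45 ± 0.42 and 2.43 ± 0.32.

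A set of 361 called segments, chosen after the values were seen, was over 8-fold higher in LIRKO_HFD than in Ctl. They took 9.32% to 12.7% of the LIRKO_HFD input reads and 0.167% to 1.65% of the Ctl ones. LIRKO input 1 held 10.9% and LIRKO input 2 held 5.88%, while LIRKO inputs 3 and 4 held 1.08% and 1.74%.

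The direction of the calls depended on the scaling. With library totals 527 segments were called higher and 2697 lower in LIRKO_HFD than in Ctl, and with this scaling the median log2 change of all segments was -0.59, in place of -0.02 with TMM. For LIRKO against Ctl the same median was -0.34 with library totals, and the split of calls was 201 higher and 128 lower. For LIRKO_HFD against Ctl, 77 were higher and 319 lower with the share of covered bins as a covariate. That share did not overlap between the inputs of LIRKO_HFD and Ctl, so the fit cannot tell breadth from condition. In that comparison leaving out 1 sample gave 746 calls without LIRKO_HFD 2 and 761 without LIRKO_HFD 1, in place of 1158.

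No m6A peak was called between LIRKO_HFD and Ctl by edgeR's quasi-likelihood test, whose lowest adjusted p after Benjamini-Hochberg adjustment was 0.0793. At an unadjusted p under 0.05 there were 4937 of 77282 peaks, and DESeq2 called 84. With library totals 5 were called and the median log2 change of all peaks was 0.27, in place of 0.01 with TMM. A fit of the 2 conditions alone called 21, and leaving out 1 sample gave 7 calls without Ctl 6, 6 without LIRKO_HFD 2, 1 without Ctl 4 and 0 without each of the others.

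The comparison of LIRKO_HFD with LIRKO concerns the factor added to the knockout, for which the series has no Ctl group. Reads on the Y chromosome also set these groups apart. If they reflect the sex of the animals, which the labels do not give, HFD and sex cannot be separated in any comparison with LIRKO_HFD. In 32 segments between chrY:899469-1286632 the Ctl inputs had 34.2 ± 8.57 CPM of the library total (SD, n = 6), the 4 LIRKO inputs 10.6 to 53.9, and the LIRKO_HFD inputs 0.0499 ± 0.0487 (n = 4). The LIRKO_HFD counts were 0 to 18 reads, 32 over the 4 inputs, and those of the other inputs 1779 to 9321. Of the 36 segments called in this comparison 32 lay on the Y chromosome and were lower in LIRKO_HFD, with a lowest adjusted p of 1.53e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A region of the X chromosome, chrX:102504141-102526818, was higher in LIRKO_HFD, at 190 ± 17.5 CPM against 89.1 ± 33.7 in Ctl. Its LIRKO levels were 71.6 and 83.6 in inputs 1 and 3, but 0.179 in input 2 (95% exact interval 0.122 to 0.254) and 0.584 in input 4 (0.475 to 0.709). Both regions were chosen after their values were seen.

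**Figure D3:**
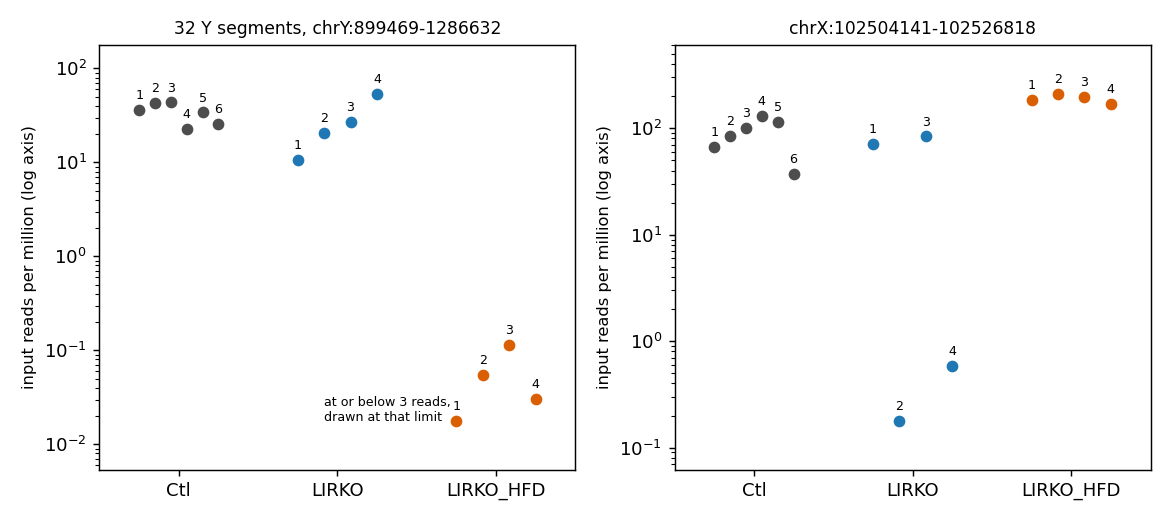
Input CPM (log axis) in 32 segments of chrY:899469-1286632 and in chrX:102504141-102526818, with each point an input library numbered by replicate. The LIRKO_HFD inputs had 0 to 18 reads in the Y segments, and the input without any is drawn at the limit of 3 reads.

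The other 4 called segments were higher in LIRKO_HFD than in LIRKO, and they were chosen after their values were seen. At chr8:85388209-85389486 the input level was 1.85 ± 0.39 log2 CPM (SD, n = 4) in LIRKO_HFD, 0.57 ± 0.13 (n = 4) in LIRKO and 0.66 ± 0.36 (n = 6) in Ctl. At chr9:59817023-59820150 it was 1.46 ± 0.12, 0.46 ± 0.29 and 1.04 ± 0.22 in the same order. At chr3:108392853-108393052 it was -1.19 ± 0.39, -3.81 ± 0.33 and -2.28 ± 0.41. At chr19:5255197-5255446 it was -2.55 ± 1.05, -7.14 ± 0.41 and -3.31 ± 1.37, with LIRKO near the floor of the scale. Their adjusted p-values were 0.0277, 0.0376, 0.00194 and 0.038 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the Y chromosome left out only chr3:108392853-108393052 was called, and without LIRKO 1 and 2, which held the segments described above at or near LIRKO_HFD levels, 573 segments were.

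At the m6A peaks LIRKO_HFD and LIRKO differed at 9 peaks, 3 higher and 6 lower. The log2 ratio of IP to input at chr16:94430651-94430950 was 1.03 ± 0.76 (SD, n = 4) in LIRKO_HFD and -1.12 ± 0.63 (n = 4) in LIRKO. At chr5:93112713-93113062 it was 0.58 ± 0.17 and -0.53 ± 0.19. It was lower in LIRKO_HFD at chr12:102547197-102547296, near an abundant locus, at -0.01 ± 0.09 against 1.99 ± 0.79, and at chr18:20815667-20816066, at -1.04 ± 0.26 against 0.31 ± 0.47. The fitted log2 changes were 2.12 (adjusted p = 0.049), 1.11 (0.035), -2.05 (0.0326) and -1.36 (0.035) in that order, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. None of the 9 was called with library totals, where 0 peaks were called with the same tool and 11196 had an unadjusted p under 0.05, against 9529 in the TMM fit. DESeq2 called 1488. Leaving out 1 sample gave 740 calls without LIRKO 2, 98 without LIRKO_HFD 2, 1 without LIRKO_HFD 4 and 0 without each of the other 5 samples.

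The deposited lists held 74915 ± 17140 peaks (SD, n = 6) per Ctl sample, 39021 ± 16215 (n = 4) per LIRKO sample and 46837 ± 4542 (n = 4) per LIRKO_HFD sample. The mean of LIRKO differed from that of Ctl by -35894 peaks, with an exact two-sided permutation p of 0.0143 (adjusted 0.0643 over 18 tests). LIRKO_HFD differed from Ctl by -28078 (exact permutation p = 0.019, adjusted 0.0686), and LIRKO_HFD and LIRKO did not differ beyond the spread (exact permutation p = 0.429). With a minimum height of 73 reads per bin for all lists, the highest of the lists' own lowest heights, the means were 43726, 32653 and 35001, and the differences from Ctl were -11073 and -8725 peaks (exact permutation p = 0.0381 for both). The p for LIRKO against Ctl was 0.0595 without LIRKO 2, and that for LIRKO_HFD against Ctl was 0.0595 without LIRKO_HFD 1, 3 or 4, by the same exact test.

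The length of a list follows in part from how it was made. In each list 89.9% to 90.0% of the bins with reads in both libraries lay below the lowest peak height, so a library with more covered bins had more bins open to peaks. The relation of list length to the share of genome bins with m6A reads was therefore largely set beforehand, and its p-values are no evidence beyond that. Over the 14 samples Pearson's r was 0.928 (permutation p = 1e-05, the smallest that 100000 resamples give) and Spearman's rho was 0.903 (permutation p = 3e-05). Without Ctl 1 and Ctl 2, the samples farthest from the median breadth, r was 0.891 (permutation p = 0.0004). Within the 6 Ctl samples r was 0.852 (exact permutation p = 0.0333) and rho was 0.771, and the other groups were too small for a value of their own. This was the only relation of this kind computed.

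**Figure D4:**
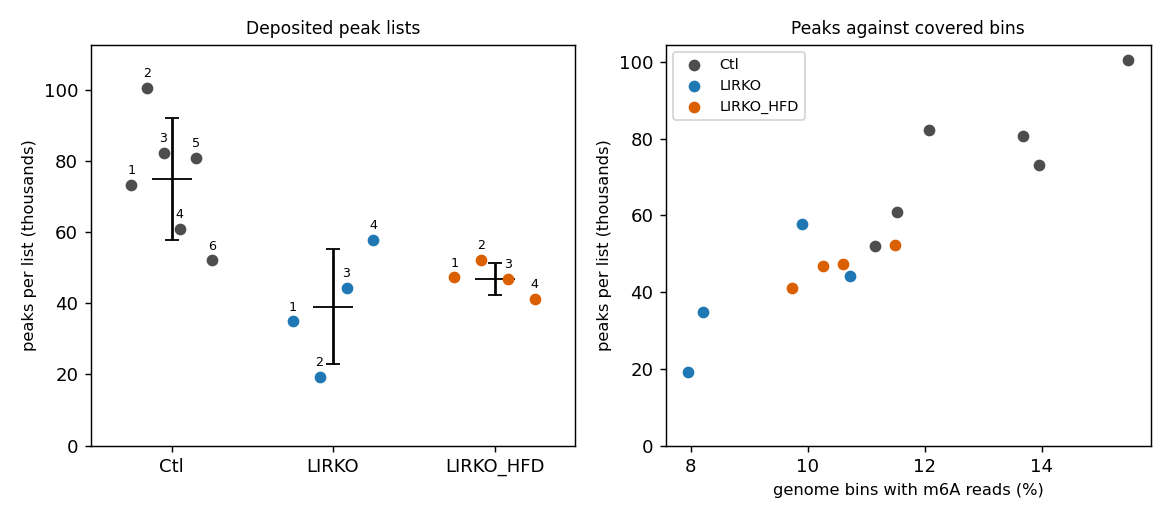
Left, peaks per deposited list in each sample, with bars for the mean ± SD of each condition; right, peaks per list against the share of genome bins with m6A reads (%). Points are samples numbered by replicate, and Ctl 2 had 100470 peaks and LIRKO 2 had 19193.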

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

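All tests weighed in this part were chosen only after the results had been seen. Chance alone marks about 1 in 20 groups for a sample far from the others, which is 5.4 of the 108 groups tested, and 8 values were marked.

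In Ctl 6 the 100 most covered bins held 55.2% of the input reads, far from the 42.4% to 47.2% of the other Ctl inputs. In Ctl 3 the 361 segments over 8-fold higher in LIRKO_HFD than in Ctl held 1.65% of the input reads, and 0.167% to 0.677% in the other Ctl inputs. At chr19:5255197-5255446 LIRKO 4 had -6.52 log2 CPM, while the other LIRKO inputs lay at the floor of -7.35. At chr1:22594975-22595074 the log2 ratio of IP to input was 11.17 in LIRKO_HFD 4, a value set by the prior count since its input had 0 reads there, and 3.36 to 4.62 in the other LIRKO_HFD samples. At chr5:93112713-93113062 that ratio was -0.25 in LIRKO 2, away from -0.65 to -0.59 in the other LIRKO samples, and 0.83 in LIRKO_HFD 1, away from 0.47 to 0.52. At chr18:20815667-20816066 it was -0.23 in Ctl 1, with -0.83 to -0.64 in the other Ctl samples, and -0.39 in LIRKO 2, with 0.47 to 0.62 in the other LIRKO samples.

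The LIRKO_HFD inputs had 0 to 18 reads in the 32 segments of the Y chromosome. Depth as the cause is argued against, since the lowest rate of the other inputs predicts 1665 reads at the depth of a LIRKO_HFD input. A swap with Ctl or LIRKO samples is also argued against, because 0 of the 10 Ctl and LIRKO inputs had Y reads at the LIRKO_HFD level. A candidate explanation is the sex of the animals, which the labels do not give: the X region was at 170 CPM or more in each LIRKO_HFD input and at 0.179 to 130 in the other inputs, all of which had Y reads. If so, sex and HFD cannot be separated in this series, differences of LIRKO_HFD from the other groups may come from either, and the range of the X region leaves open a mix of sexes among the Ctl and LIRKO samples. However, the 2 inputs with almost no X region reads, LIRKO 2 and 4, ranked 1 and 9 in Y reads among the 10 Ctl and LIRKO inputs. The X and Y regions therefore did not run together in those 2 inputs, as a mix of sexes alone would have it.

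The 361 segments over 8-fold higher in LIRKO_HFD than in Ctl were also high in LIRKO inputs 1 and 2 and low in LIRKO inputs 3 and 4. The choice between TMM and library totals is too small to make such changes. With library totals the median log2 change of all segments, LIRKO_HFD against Ctl, was -0.59 in place of -0.02. The lowest log2 change of the 361 was then 2.42, and 358 were called. That count is no further evidence, since segments chosen for changes over 8-fold had to stay high under so small a shift. LIRKO 1 and 2 being LIRKO_HFD samples is argued against by their Y reads, 10.6 CPM or more, when no LIRKO_HFD input passed 0.115. RNA from 1 added source or programme stays open. In LIRKO 1 and 2 the 226 segments with a LIRKO_HFD mean of at least 1 CPM kept nearly their LIRKO_HFD ratios. The interquartile range of their log2 ratio was at most 0.387, and the other segments were not compared. Whether such a source lies in the islets or in tissue isolated with them could not be tested without gene names. With the share of covered bins as a covariate only 15 of the 361 segments were called. The median log2 change of all 361 was then 3.40 in place of 4.65. Covered bins did not overlap between LIRKO_HFD and Ctl inputs, so the lost calls do not show that breadth was the cause.

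Of 100 splits of the Ctl and LIRKO inputs 4 made at least the 672 calls of the labels, with up to 4887 when Ctl 6 and LIRKO 4 changed places, which points to a structure of the samples. Breadth of the libraries is a candidate explanation: on the axis of those 4887 segments the LIRKO_HFD inputs, which did not set it, lay at 0.65 ± 0.14 (SD, n = 4), toward the inputs with few covered bins. That end was set by LIRKO 1, 2 and 3 with Ctl 6, and LIRKO_HFD shares the knockout label with LIRKO. The position therefore cannot tell breadth from RNA that these groups share. The m6A went the way of the labels, with 9 calls when Ctl 6 and LIRKO 4 were exchanged and 212 as labelled. However, 1 other split, in which LIRKO 2 and Ctl 3 changed places, made 2129. Exchanged labels of these samples cannot be told apart from breadth: on an axis of 500 m6A peaks set without them, 0 at the other Ctl and 1 at the other LIRKO samples, Ctl 6 lay at 0.182 and LIRKO 4 at 0.658, as labelled, but LIRKO 4 passed 0.5 by less than the SD of 0.198 among 3 LIRKO samples left out likewise. A biological difference between the groups stays open as untested.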

How the results depend on the processing

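Alternatives chosen after the data were seen were the 10-kb windows, the 200-bp joining, regions near abundant loci or on Y left out, the covered-bins covariate, the minimum peak heights, the forms of the mitochondrial and covered-bin shares, 5 of the enrichment settings, and the joint sample exclusions. Where no cause is named below, the cause was not tested.

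For RNA, library totals gave 329 calls for LIRKO against Ctl and 3224 (527 higher, 2697 lower) for LIRKO_HFD against Ctl. A mean log2 CPM of at least 1, which tests fewer segments, gave 582 for LIRKO_HFD against Ctl and 1 for LIRKO_HFD against LIRKO. DESeq2 gave 2926, 2101 and 150 for LIRKO against Ctl, LIRKO_HFD against Ctl and LIRKO_HFD against LIRKO. The covered-bins covariate gave 109, 396 and 92 in that order. For LIRKO against Ctl, 10-kb windows gave 1951 calls, the 2 conditions alone 0 (12379 at an unadjusted p under 0.05), LIRKO 1 and 2 left out 0 (6185), and Ctl 6 and LIRKO 4 left out 5393, which gave 1872 for LIRKO_HFD against Ctl. For LIRKO_HFD against LIRKO, segments joined over 200 bp gave 59 calls, the Y chromosome left out 1, and LIRKO 1 and 2 left out 573. Leaving out 1 sample gave 0 (without LIRKO 1 or 2) to 2225 (without Ctl 6), 746 (without LIRKO_HFD 2) to 1479, and 29 to 41 calls.

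The replicate numbers do not pair the samples: inputs of the same number in different conditions correlated in their deviations from the group means at -0.47 to 0.13 over 12 pairs, and other pairs at -0.47 to 0.62. The replicate block gave 0 RNA calls for LIRKO against Ctl (12123 at an unadjusted p under 0.05), 465 for LIRKO_HFD against Ctl and 23 for LIRKO_HFD against LIRKO. Without the replicate block of IP and input, m6A calls were 9 for LIRKO against Ctl and 0 for LIRKO_HFD against LIRKO (6065 at an unadjusted p under 0.05), by edgeR.

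For m6A calls of LIRKO against Ctl, library totals gave 95, a mean log2 CPM of at least 1 gave 446, DESeq2 1355, the 2 conditions alone 137, LIRKO 1 and 2 left out 496, and Ctl 6 and LIRKO 4 left out 90. For LIRKO_HFD against Ctl the same settings, in order and without the exclusion of LIRKO 1 and 2, gave 5, 2, 84, 21 and 17. For LIRKO_HFD against LIRKO they gave 0, 357, 1488, 0, 219 and 0, while DESeq2 size factors gave 17, peaks in at least 7 samples 88, peaks in at least 1 sample 0, thinned counts 3, and peaks near abundant loci left out 66. Leaving out 1 sample gave 67 (without LIRKO 3) to 1413 (without LIRKO 2), 0 to 7 (without Ctl 6) and 0 to 740 (without LIRKO 2) calls. Peaks higher in IP than input in all 3 conditions numbered 63896 with library totals, 8721 at a mean log2 CPM of at least 1, and 12520 of the peaks in at least 7 samples, the last 2 from fewer peaks tested.

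Peak numbers kept their direction in all settings run. With a minimum height relative to the m6A total LIRKO_HFD differed from Ctl by -7219 (exact permutation p = 0.0524). Leaving out 1 sample gave -42136 to -29285 for LIRKO against Ctl, -32660 to -22967 for LIRKO_HFD against Ctl and 1207 to 14058 for LIRKO_HFD against LIRKO. The mitochondrial share of the m6A libraries differed by -0.62 between LIRKO_HFD and LIRKO (exact permutation p = 0.314), and leaving out 1 sample gave -0.902 to -0.0272, -1.88 to -1.61 and -1.73 to -0.859 in the inputs. Covered bins of LIRKO_HFD against LIRKO changed sign without LIRKO 1 (-0.323), LIRKO 2 (-1.03) or LIRKO_HFD 2 (-0.0704), from 0.155 with all samples, and leaving out 1 sample gave -1.03 to 1.35. No named region changed direction. Depth limits segments and peaks near the floor, and the simulated 2-fold changes were mostly missed.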

Other observations

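The counts of calls were compared with those of other splits of the same samples, and all these tests were chosen after the calls had been seen. For the RNA of LIRKO_HFD against Ctl 1 of 100 splits drawn from 210, the real one, made as many calls as the labels (1158, highest other 0). This argues against chance among the splits run, which were not all. For LIRKO_HFD against LIRKO it was 1 of 35 (36, highest other 0). Of those 36 calls 32 lay on the Y chromosome, so the second result mostly restates the difference in Y reads, which had already been seen. These shares were not adjusted for the number of such tests. The remaining segments were not tested apart, and neither result tells HFD from another difference between these samples. For the RNA of LIRKO against Ctl 4 of 100 splits drawn from 210 made as many calls (672, highest other 4887). That share was under 0.05, but only part of the splits was run, and the 672 calls lay below those of 3 other splits. Chance was therefore not excluded, and the structure described above rather than the labels may have set the number of calls.

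For the m6A of LIRKO against Ctl 2 of 22 splits made as many calls (212, highest other 2129), so chance was not excluded. A split with about 10 times the calls of the labels points to a structure of the samples. That split differed from the labels only in that LIRKO 2 and Ctl 3 changed places. Leaving LIRKO 2 out gave 1413 calls, so the number of calls depended strongly on this sample. For LIRKO_HFD against Ctl all 22 of 22 splits made at least the 0 calls of the labels (highest other 1), which leaves nothing to test. For LIRKO_HFD against LIRKO 1 of 22 splits drawn from 35 made as many calls (9, highest other 5). That is the smallest share this draw can give, and the other splits were not run, so chance was not excluded.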
